A study of Arabidopsis thaliana with 6 samples.

How the data were processed

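Transcript levels were measured with Affymetrix expression arrays on total RNA from seedlings of the Arabidopsis thaliana accession Col-0, a widely used laboratory strain of this small flowering plant. The table held 22810 probe sets on each of 6 arrays. A probe set is a group of short oligonucleotides on the array that report on one transcript. Of the arrays, 3 came from seedlings kept in darkness without heat (control) and 3 from seedlings exposed to 37 °C for 30 min in darkness (heat), per the labels. The series design also names groups treated in the light, which were not analysed here.

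The deposited values were on a log2 scale and were taken as the authors gave them. RMA, a method that corrects background, equalizes the arrays and summarizes the probes of a probe set, is the only tool named in the submitters' processing notes, and its software and version are not given in the sources used here. The array medians of the deposited log2 values lay between 2.78 and 2.94 and the largest value was 12.33. Such medians are lower than RMA commonly gives, and the background step is not given in the sources used here, so the size of the large log2 differences rests on a step that could not be examined. A second table from the authors held the same log2 values per array (largest gap 0) together with linear ratios. Each deposited ratio set 1 heat array over the control array with the same replicate number, and it matched the log2 values to within a relative gap of 6.3e-05. The p-value columns of that table were empty. The arrays carry no read depth. Their number limits the precision, and neither table gave a detection call, so a value near the bottom of an array's range cannot be told from background and a fold against it depends on that background.

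Probe sets were named through the gene identifiers of the authors' table, matched to a reference gene table of the TAIR10.1 assembly. Of the probe sets, 20653 pointed to 1 gene (20482 of these matched the reference and 171 did not), 959 pointed to several genes, 1134 to none, and 64 were control probe sets. The build behind the array annotation is not given in the sources used here, so no coordinates are printed. The 64 control probe sets were left out, and 22746 were tested. For values per gene, the brightest probe set matching that locus alone was used. A probe set shared by several loci was used only where a locus had no other.

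The comparison was heat minus control, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, 3 against 3 arrays). The test was two-sided, with Benjamini-Hochberg adjustment over the 22746 probe sets and a threshold of 0.05 on adjusted p. Counts with an absolute log2 difference of at least 1 are given beside it. All adjusted p-values of single genes come from this limma fit. Every SE is limma's moderated standard error of the log2 difference. Nothing in the labels says that the replicates came from separately grown plants, so the p-values measure only the spread between these samples, which may be technical.

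Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 24 lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes, while fry tests a list against no change. The lists, from general knowledge and fixed before the data were examined, covered small heat shock proteins, HSP70, HSP90 and HSP100 chaperones, co-chaperones, heat shock factors, endoplasmic reticulum chaperones, DREB and cold or drought genes, reactive-oxygen enzymes, galactinol and trehalose synthesis, light signalling, photosynthesis, the clock, auxin, abscisic acid, early stress and touch genes, jasmonate, defence, dark and sugar starvation, SR splicing factors, the cell cycle, cell wall expansion, reference genes and root markers. Lists of plastid-encoded and mitochondrially encoded genes were taken by rule. The rule was written for locus names and matched none for mitochondria, so the gene symbols of the authors' table were used there and the chromosome in the reference for plastids. A list of cytosolic ribosomal proteins by title found 3 genes and was not tested. HSP17.4A, HSP70-4 and HSP70-5 were left out of the list tests because the reference gives their loci other symbols. Counts called "adjusted over the list alone" repeat the adjustment within a list.

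The genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls past the threshold whose 3 heat arrays all lay beyond all 3 control arrays, up to 2 rises and 2 falls in each list, and a fixed set of heat, light, clock and reference genes whatever their value. PIF7 had no matched probe set. A planned test of promoter motifs needed a genome, which was not used here, and was not run.

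The pipeline was tested on simulated data with the means of these arrays and their residual spreads shuffled among probe sets, 22746 probe sets in all. Of 50 probe sets shifted by 1 on the log2 scale, 31 were called, against 3 of 50 shifted by 0.5, 45 of 50 shifted by 2 and 49 of 50 shifted by 4. Of 134 calls, 6 fell on unchanged probe sets. The simulated arrays had no array with a wider spread and no level-dependent difference between the groups, so this share need not hold for the real calls. Of 20 simulated lists, both shifted ones were called in the right direction and 0 of the others. Each probe set was drawn independently, so the simulated lists had no correlation between genes. The estimated correlation in the real lists reached 0.41, a case that this simulation does not test. Alternatives tried were the replicate number as a block, median centring, a new quantile normalization, cyclic loess, filters on dim probe sets, other variance moderation, a size threshold inside the test, the age given in the labels as a covariate, and each array left out in turn. Cyclic loess was added after a level-dependent difference between the groups was seen. Figures were drawn with matplotlib 3.10.9.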

Results

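The study asked how the transcriptome of Arabidopsis seedlings responds to heat stress and how light and temperature signalling interact. The arrays analysed here covered the dark part of that design. Seeds were kept at 4 °C for 72 h and then grown on solid medium at 23 °C with 16 h of light and 8 h of darkness per day. The design text puts the seedlings at 10 days of age. The sample labels instead give a different age to each array, 16, 17 and 18 days for control replicates 1 to 3 and 19, 20 and 21 days for heat replicates 1 to 3, so every heat array carries an older label than every control array. Pearson correlations over all probe sets were 0.989 to 0.991 among the heat arrays, 0.976 to 0.988 among the control arrays and 0.941 to 0.954 between groups. Control replicate 2 had the lowest correlations with the other controls.

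Small heat shock proteins, chaperones that hold unfolded proteins without using ATP, gave the largest rises after heat. HSP17.6A rose from 2.19 ± 0.10 to 11.27 ± 0.07 on the log2 scale (SD, n = 3 arrays per group), a difference of 9.08 (SE 0.11, limma adjusted p = 1.91e-08). HSP17.6II rose by 8.83 (SE 0.10), HSP17.6C by 8.51 (SE 0.14), HSP26.5 by 8.50 (SE 0.13), HSP17.4 by 8.49 (SE 0.13), HSP17.4B by 8.23 (SE 0.13), HSP15.7 by 8.06 (SE 0.16), HSP22.0 by 8.03 (SE 0.11) and the plastid protein HSP21 by 7.82 (SE 0.18). The probe set shared by HSP17.6A-CI and HSP17.8 rose by 9.41 (SE 0.15). Of 16 probe sets in the list, 13 rose, 0 fell and 3 did not pass the test, with 13 rising when adjusted over the list alone. The 3 that did not pass were HSP15.4 (-0.47, SE 0.40), HSP14.7 (0.11, SE 0.11) and HSP21.7 (0.19, SE 0.17). The list median was 8.01 (camera adjusted p = 5.1e-38, and adjusted p = 0.00589 with an estimated correlation). Control levels of the risen members ranged from the 11.1th percentile of all probe sets (HSP17.6II) to the 67.3th (HSP23.5, chosen after its values were seen), and the folds of the low ones depend on the background of the arrays.

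Most ATP-dependent chaperones rose. HSP101, a disaggregase required for acquired thermotolerance, rose by 8.19 (SE 0.23, limma adjusted p = 6.08e-07), HSP70T-2 by 7.64 (SE 0.16), HSP90.1 by 7.21 (SE 0.33) and HSP70-4 by 6.34 (SE 0.47). Of 18 probe sets for HSP70, HSP90 and HSP100 proteins, 14 rose, 0 fell and 4 did not pass, and 17 rose and 1 fell when adjusted over the list alone. Their median difference was 2.32 (camera adjusted p = 1.34e-26, and 0.0301 as adjusted p with an estimated correlation). Among co-chaperones and other thermotolerance genes, 13 of 16 rose and 0 fell, with the same count adjusted over the list alone. BAG6, a calmodulin-binding co-chaperone, rose by 8.64 (SE 0.14), the peptidyl-prolyl isomerase ROF2 by 7.97 (SE 0.20) and the transcriptional coactivator MBF1C by 7.37 (SE 0.32). The co-chaperone median was 3.83 (camera adjusted p = 5.19e-26, but adjusted p = 0.0514 with an estimated correlation). Control arrays differed for some of these genes. HSP70-4 read 5.60, 3.54 and 5.17 on control replicates 1, 2 and 3 against 11.13, 11.15 and 11.05 on the heat arrays.

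Heat shock transcription factors split into strongly raised and little changed members. HSFA2, which sustains the heat response, rose by 7.64 (SE 0.27, limma adjusted p = 2.53e-06), HSFA7A rose by 6.29 (SE 0.15) and HSFB1, read by a shared probe set, by 4.39 (SE 0.33). The A1 factors that start the response gave unlike calls, and differences between these members were not tested. HSFA1E, chosen after its values were seen, rose by 0.83 (SE 0.13, adjusted p = 0.0116), a call that ended without heat replicate 1 (0.82, adjusted p = 0.0575) or 2 (0.79, adjusted p = 0.0606). HSFA1A stood at 2.11 ± 0.12 in controls and 2.02 ± 0.22 after heat (limma adjusted p = 0.763) and HSFA1B at 2.93 ± 0.13 and 2.72 ± 0.17 (adjusted p = 0.409). HSFA1D rose by 0.78 (SE 0.17, adjusted p = 0.0407), a call that ended without control replicate 1 or 3 or heat replicate 1 or 2 (0.66 to 0.93 over the arrays left out, adjusted p up to 0.144). Of the 21 factors, 10 rose, 1 fell and 10 did not pass, and 11 rose and 1 fell when adjusted over the list alone. The list median was 0.54 (camera adjusted p = 5.06e-09, and adjusted p = 0.0301 with an estimated correlation). The one that fell was HSFA4C (-0.62, SE 0.13, adjusted p = 0.0355), and its call ended with any array other than control replicate 2 left out (adjusted p up to 0.134), with the arrays centred on their medians (-0.51), after cyclic loess (-0.46) and with a trend in the moderation.

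**Figure D1:**
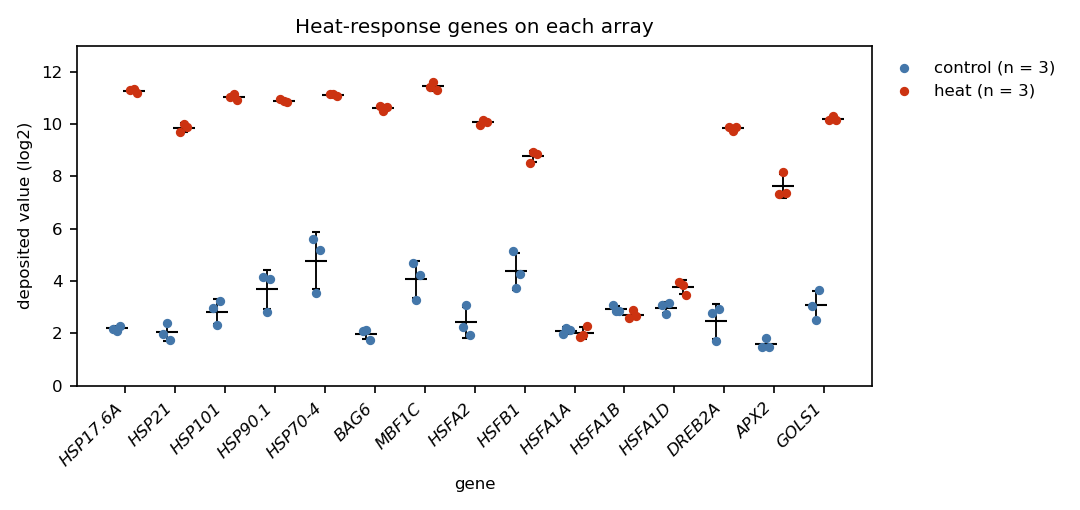
Deposited log2 values of 15 heat-response genes (x axis) on each of the 3 control and 3 heat arrays; points are single arrays, horizontal marks are group means and bars are 1 SD. The 3 heat arrays lie above the 3 control arrays for HSP17.6A, HSP101, HSFA2 and the other genes shown apart from HSFA1A and HSFA1B.

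Genes of other stress pathways rose with the chaperones. DREB2A, a transcription factor of the dehydration response, rose by 7.36 (SE 0.30, limma adjusted p = 5.82e-06) and its homologue DREB2B by 2.02 (SE 0.17). In the DREB and cold or drought list 4 of 13 probe sets rose and 0 fell, with 5 rising when adjusted over the list alone (median 0.21, camera adjusted p = 2.67e-05, adjusted p = 0.0802 with an estimated correlation; median 0.14 without heat replicate 3). The zinc finger genes ZAT12 and ZAT10 rose by 4.95 (SE 0.15) and 3.17 (SE 0.27) among 14 early stress and touch genes, of which 3 rose and 0 fell, or 5 rose when adjusted over the list alone (median 0.17, camera adjusted p = 0.000572, adjusted p = 0.135 with an estimated correlation). The early stress median was 0.09 without control replicate 2, 0.27 without control replicate 3 and 0.29 without heat replicate 2. GOLS1 and GOLS2, galactinol synthases that make precursors of raffinose sugars, rose by 7.14 (SE 0.26) and 3.496 (SE 0.20). They were the 2 that rose of 12 galactinol and trehalose genes, also when adjusted over the list alone. That list was not shifted (median -0.15, mean 0.70, camera direction up, adjusted p = 0.214), but it passed as higher without control replicate 1 (median 0.03, adjusted p = 0.031) and with the labelled age as a covariate (adjusted p = 0.00816). Tested against no change rather than against other genes, it passed as higher (fry adjusted p = 0.0455). The cytosolic ascorbate peroxidase APX2 rose by 6.03 (SE 0.23, limma adjusted p = 4.08e-06). It alone passed among 17 reactive-oxygen enzymes, though 4 rose and 3 fell when adjusted over the list alone (median -0.06, mean 0.19, camera direction up, adjusted p = 0.412, but fry adjusted p = 0.0234), and the median was -0.21 without control replicate 1, 0.21 without control replicate 2, -0.14 without heat replicate 1, -0.0034 without heat replicate 2 and 0.04 without heat replicate 3. WRKY70, a regulator of salicylate signalling, rose by 2.33 (SE 0.20), the only one of 13 defence genes to pass, also when adjusted over the list alone (median 0.07, camera adjusted p = 0.315; median 0.01 without control replicate 1 or 3 and 0.03 without heat replicate 2).

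In the endoplasmic reticulum list, the co-chaperone ERDJ3A rose by 6.59 (SE 0.12, limma adjusted p = 4.31e-08) and TIN1, a gene induced by tunicamycin, by 6.28 (SE 0.15). The transducer BZIP60 read 5.60 ± 0.37 in controls and 5.07 ± 0.13 after heat (adjusted p = 0.164), a difference that passed as a fall only without control replicate 2 (-0.74, adjusted p = 0.0111). BIP3, an inducible luminal chaperone, read 1.57 ± 0.21 and 1.597 ± 0.07 (adjusted p = 0.915), a difference that turned sign without control replicate 1 (-0.0052) or 3 (-0.0499) or heat replicate 2 (-0.0061). Of 21 probe sets, 5 rose and 1 fell, or 5 rose and 4 fell when adjusted over the list alone. The fall was calreticulin CRT1A (-0.81, SE 0.15, adjusted p = 0.0196), a call that ended without control replicate 1 or 3 or heat replicate 1 or 3 (adjusted p up to 0.0829). The list median was 0.03 (camera adjusted p = 0.0223, adjusted p = 0.521 with an estimated correlation), and the list call ended without control replicate 2 (median 0.07, adjusted p = 0.0894) or heat replicate 2 (median -0.0061, adjusted p = 0.148). That median was 0.06 without control replicate 3 and 0.07 without heat replicate 1 or 3. Among 18 SR splicing factors, SR45A rose by 5.04 (SE 0.12, adjusted p = 2.5e-07) and SR30 by 2.35 (SE 0.25). In all, 3 rose and 0 fell, or 4 rose when adjusted over the list alone (median 0.18, camera adjusted p = 2.67e-05, adjusted p = 0.0514 with an estimated correlation). Abscisic acid genes included the transcription factor ABF3 (1.03, SE 0.16, adjusted p = 0.0103), the phosphatase ABI2 (0.72, SE 0.15, adjusted p = 0.0349) and the receptor PYR1 (-0.68, SE 0.13, adjusted p = 0.0246), which were the 2 rises and 1 fall among 19, or 3 and 1 when adjusted over the list alone. Their calls ended with heat replicate 2 left out (adjusted p = 0.0564 for ABF3). Over all single arrays left out, the adjusted p reached 0.131 for ABI2 and 0.109 for PYR1. ABI2 also lost its call with control replicate 1 or 3 or heat replicate 1 or 3 left out, and PYR1 with control replicate 1 or heat replicate 3 left out, with the arrays centred on their medians and after cyclic loess. The list median was 0.34, and 0.21 without heat replicate 3 (camera adjusted p = 0.00253, adjusted p = 0.112 with an estimated correlation and 0.132 with the labelled age as a covariate).

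Clock genes moved in different directions. LNK1, a morning-phased coactivator, rose by 3.39 (SE 0.16, limma adjusted p = 1.57e-05) and PRR7, a repressor of the morning loop, by 3.03 (SE 0.11). LUX, an evening complex gene read by a shared probe set, rose by 1.28 (SE 0.23, adjusted p = 0.0179) and CCA1 by 0.76 (SE 0.13, adjusted p = 0.0143). The blue-light receptor FKF1 fell by 1.09 (SE 0.22, adjusted p = 0.0269). LHY read 2.61 ± 0.48 in controls and 2.52 ± 0.13 after heat (adjusted p = 0.853, the sign turning without control replicate 2, 0.19), TOC1 read 5.23 ± 0.18 and 4.84 ± 0.12 (adjusted p = 0.14) and ELF3 read 5.40 ± 0.35 and 5.79 ± 0.14 (adjusted p = 0.278). Without control replicate 2, TOC1 (-0.50, adjusted p = 0.0356) and ELF3 (0.56, adjusted p = 0.0426) passed. The call of LUX ended without heat replicate 2 or 3 (adjusted p up to 0.0844), that of CCA1 without control replicate 3 or heat replicate 2 or 3 (up to 0.0618) and that of FKF1 without any array other than control replicate 2 (up to 0.113). Of 19 clock probe sets, 5 rose and 1 fell, or 7 rose and 3 fell when adjusted over the list alone (median 0.21, camera adjusted p = 0.000503, adjusted p = 0.0514 with an estimated correlation).

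Light-signalling genes did not shift as a list (median -0.27, mean -0.04, camera direction down, adjusted p = 0.586), a direction that turned after quantile normalization, after cyclic loess and without control replicate 3 (median -0.12), though single members passed. BBX22, a B-box activator of photomorphogenesis, rose by 2.79 (SE 0.17, limma adjusted p = 5.79e-05). The phytochrome-interacting factors PIF5 and PIF4 rose by 1.31 (SE 0.17, adjusted p = 0.00389) and 0.63 (SE 0.12, adjusted p = 0.0213). PAR1 fell by 0.92 (SE 0.14, adjusted p = 0.00809) and the red-light receptor PHYB by 0.74 (SE 0.16, adjusted p = 0.0398). Of 27 probe sets, 3 rose and 2 fell, also when adjusted over the list alone. HY5 read 3.35 ± 0.40 in controls and 3.39 ± 0.13 after heat (adjusted p = 0.922, the sign turning without control replicate 1, -0.10, control replicate 2, -0.0381, or heat replicate 2, -0.0006), CRY1 read 4.97 ± 0.09 and 4.54 ± 0.49 (adjusted p = 0.33) and COP1 read 4.88 ± 0.15 and 4.56 ± 0.13 (adjusted p = 0.199). The calls of PIF4 (adjusted p up to 0.0855) and PHYB (up to 0.131) each ended without control replicate 1 or 3. PIF4 also lost its call without heat replicate 1 or 3, and PHYB without heat replicate 2 or 3, with the arrays centred on their medians, after quantile normalization and after cyclic loess.

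**Figure D2:**
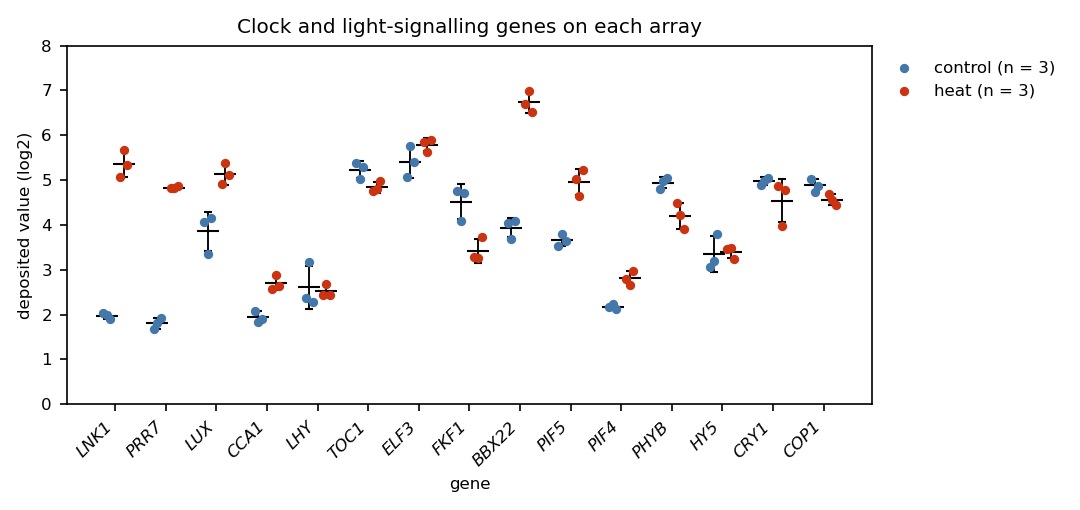
Deposited log2 values of 15 clock and light-signalling genes (x axis) on each of the 3 control and 3 heat arrays; points are single arrays, horizontal marks are group means and bars are 1 SD. LNK1, PRR7 and BBX22 show the widest gaps between the groups, and the points of LHY, ELF3 and HY5 overlap.

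The falls were smaller than the rises. DIN2, a beta-glucosidase induced by darkness and sugar shortage, fell by 3.83 (SE 0.76, limma adjusted p = 0.0269) from 7.31 ± 1.80 to 3.48 ± 0.15, and its call ended without any single heat array (adjusted p up to 0.118). The histone genes HTA13 (H2A) and HTB1 (H2B) fell by 2.89 (SE 0.24, adjusted p = 0.000432) and 2.72 (SE 0.15, adjusted p = 3.43e-05). EXPA1, an expansin that loosens cell walls, fell by 2.58 (SE 0.13) and the glycosyl hydrolase GH9C2 by 2.51 (SE 0.29). The GRAS factor HAM1, which maintains shoot stem cells, fell by 2.304 (SE 0.13) and the homeobox gene HB5 by 2.27 (SE 0.16). Of the genes without a functional name, AT5G54370 fell by 3.39 (SE 0.56), AT2G14460 by 2.48 (SE 0.25) and AT2G18980 by 2.27 (SE 0.45). The call of AT5G54370 ended without heat replicate 1 or 3 (adjusted p up to 0.0676) and that of AT2G18980 without control replicate 3 or any single heat array (up to 0.109).

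The list of expansins and xyloglucan endotransglucosylases was lower, with 4 of 14 falling, 3 of them expansins, and 0 rising, or 7 falling when adjusted over the list alone (median -0.56, camera adjusted p = 9.95e-05, adjusted p = 0.0514 with an estimated correlation). EXPA4 fell by 1.93 (SE 0.27, limma adjusted p = 0.00592). Of 12 cell cycle probe sets, the D-type cyclin CYCD3;1 alone fell (-1.05, SE 0.13, adjusted p = 0.0034), or 2 when adjusted over the list alone. The cell cycle list median was -0.22 (camera adjusted p = 0.0208, adjusted p = 0.221 with an estimated correlation), and its call ended after quantile normalization (0.11), after cyclic loess (0.0645), with the milder (0.108) or stricter (0.364) filter on dim probe sets, with the labelled age as a covariate (0.554) and without control replicate 2 (0.152). Dark and sugar-starvation genes did not pass as a list (median -0.36, and -0.10 without control replicate 3 and -0.19 without heat replicate 3, camera adjusted p = 0.101), with 3 falls and 0 rises among 15, or 4 falls when adjusted over the list alone, and the list passed with the arrays centred on their medians (0.0397) and without control replicate 1 (0.0346) or heat replicate 1 (0.0164) and with the labelled age as a covariate (0.0319). AILP1-like, a relative of aluminium-induced proteins, fell by 0.86 (SE 0.16, adjusted p = 0.0199), and the call ended without control replicate 1 (-0.86) or 3 (-0.77) or heat replicate 2 (-0.74) or 3 (-0.89; adjusted p up to 0.0803). SEN1 read 8.95 ± 0.23 in controls and 9.02 ± 0.43 after heat (adjusted p = 0.898, the sign turning without control replicate 2, -0.07, or heat replicate 1, -0.12) and ASN1 read 5.63 ± 0.30 and 5.88 ± 0.54 (adjusted p = 0.649). Among 18 auxin genes IAA4 alone fell, also when adjusted over the list alone (-1.38, SE 0.23, adjusted p = 0.0143, ended without any single heat array, up to 0.0725), and among 15 jasmonate genes the repressor JAZ6 alone fell, also when adjusted over the list alone (-1.26, SE 0.20, adjusted p = 0.0119, ended without heat replicate 1, 0.0563). Neither the auxin list (median 0.0022, mean -0.10, camera direction up, adjusted p = 0.987) nor the jasmonate list (median 0.07, mean -0.05, camera direction up, adjusted p = 0.646) was shifted. The auxin direction turned after each rescaling and without control replicate 2 (median 0.01) or heat replicate 2 (median -0.009), and the jasmonate direction without heat replicate 3 (median -0.06).

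Root markers bear on these falls, since whole seedlings were sampled. The list of 8 was not shifted (median -0.14, camera adjusted p = 0.572, the direction turning without heat replicate 1, median 0.009) but passed as lower with the labelled age as a covariate (median -0.76, adjusted p = 0.0494). PYK10, an abundant root beta-glucosidase, fell by 1.17 (SE 0.24, limma adjusted p = 0.0287), also when adjusted over the list alone, but lost its call without any array other than control replicate 2 (adjusted p up to 0.111) and after cyclic loess. The median level of the root markers was 4.18, 2.99 and 3.91 on control replicates 1 to 3 and 2.83, 3.19 and 4.17 on heat replicates 1 to 3, so it varied among arrays of both groups.

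Organelle transcripts were read as separate lists for mitochondria and plastids. Of 52 mitochondrially encoded probe sets, 13 rose and 0 fell, or 22 rose when adjusted over the list alone, with nad5 rising by 2.29 (SE 0.21, limma adjusted p = 0.000734) and NAD9 by 2.17 (SE 0.32, adjusted p = 0.00747), both subunits of respiratory complex I. The median level of these 52 probe sets on the control arrays was 1.80 to 1.999, near the lower quartiles of those arrays (1.76 to 1.90). Their median difference was 0.40 (camera adjusted p = 4.44e-17, adjusted p = 0.0514 with an estimated correlation). With the stricter filter on dim probe sets the median was 1.65. That filter takes the mean over control and heat arrays together, so a probe set dim in controls can pass by being high in heat. The value of 1.65 may be raised by this selection and does not measure the shift of the whole list. A 25S ribosomal RNA probe set was also higher on the heat arrays (0.79). The 3' to 5' gaps of actin and ubiquitin parted the groups in opposite directions, and that of GAPDH did not part them. The actin gap was smaller on the heat arrays. The ubiquitin gap was larger there by a narrow margin (0.25 on control replicate 2, 0.26 on heat replicate 1). For the mitochondrial values, differences in RNA or labelling could not be told apart from heat. Of 71 plastid-encoded probe sets, the photosystem I gene psaA rose (0.91, SE 0.20, adjusted p = 0.0382) and rbcL, the large subunit of Rubisco, fell (-0.74, SE 0.13, adjusted p = 0.0137), and adjusted over the list alone 0 rose and 1 fell. Both calls ended without any single heat array (adjusted p up to 0.136 for psaA and 0.0654 for rbcL). The plastid median was -0.0028 (mean 0.01, camera direction up, adjusted p = 0.412), and the list passed as higher after cyclic loess (median 0.14, adjusted p = 0.00693) and with the stricter filter on dim probe sets (median -0.0016, adjusted p = 0.0402). Nuclear photosynthesis genes had a median of 0.12, with 0 of 20 probe sets passing, also when adjusted over the list alone (camera adjusted p = 0.0119, adjusted p = 0.521 with an estimated correlation). That list call ended after quantile normalization (0.139) and without control replicate 3 (median 0.08, adjusted p = 0.0735). Without heat replicate 3 the list median was also 0.08. Tested against no change, the list did not pass (fry adjusted p = 0.235). Of 13 reference genes 0 passed, also when adjusted over the list alone (median -0.07, camera adjusted p = 0.45, direction turning after cyclic loess). ACT2 read 9.82 ± 0.18 in controls and 9.57 ± 0.06 after heat (adjusted p = 0.299), UBQ10, on a shared probe set, read 9.53 ± 0.17 and 9.82 ± 0.09 (adjusted p = 0.233) and PP2AA3 read 6.15 ± 0.27 and 6.23 ± 0.02 (adjusted p = 0.796, the sign turning without control replicate 2, -0.0763).

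**Figure D3:**
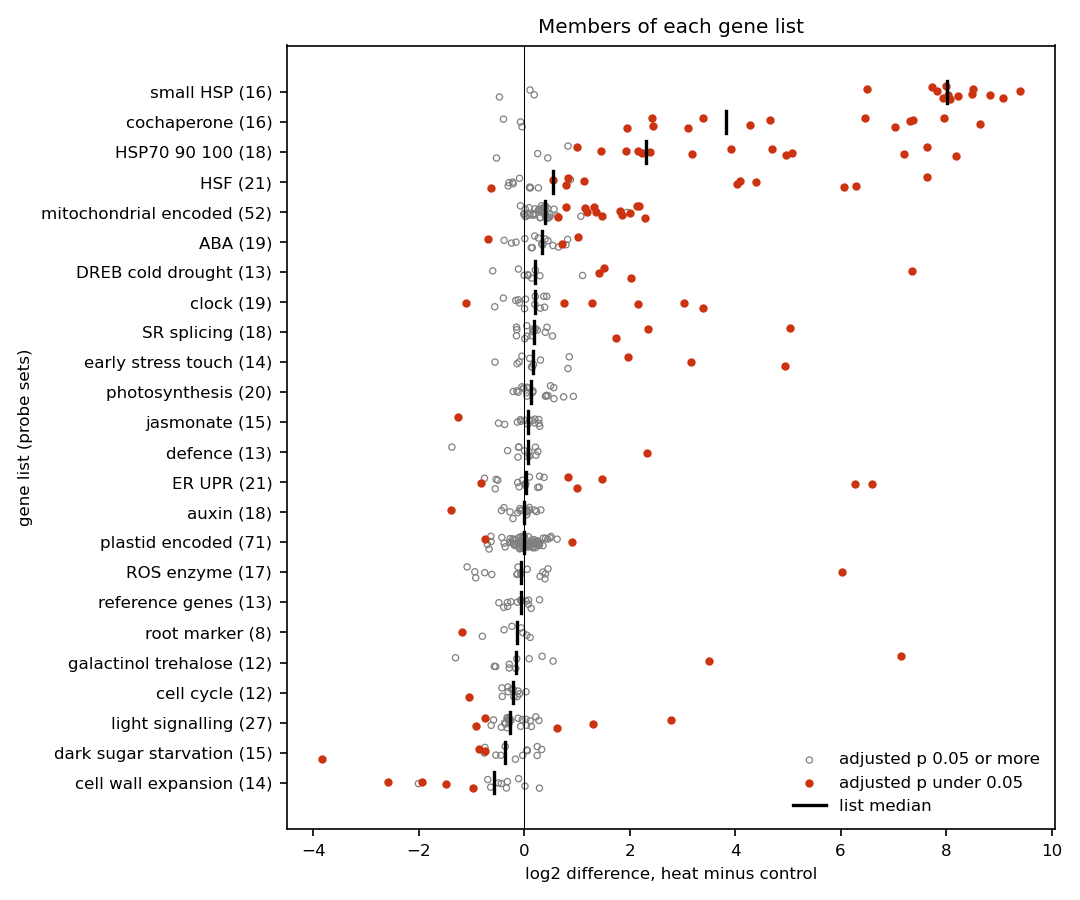
Log2 difference, heat minus control (x axis), of every probe set in 24 gene lists (y axis, number of probe sets in parentheses); filled points have a limma adjusted p under 0.05, open points do not, and the black bar is the list median. Medians are 8.01 for small heat shock proteins, 3.83 for co-chaperones, 2.32 for the HSP70, HSP90 and HSP100 list and -0.56 for cell wall expansion.

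In all, 1442 of 22746 probe sets changed (limma adjusted p under 0.05), 533 higher and 909 lower in heat, and 391 were higher and 352 lower by at least 1 on the log2 scale. Rises reached further, with 129 probe sets higher by at least 3. By gene, with 1 probe set each, 469 genes were higher and 846 lower. All 3 heat arrays lay beyond all 3 control arrays for 5972 probe sets (26.3%, where chance gives 10%). In the authors' deposited table, 307 probe sets had a ratio of at least 2 in all 3 array pairs and 123 a ratio of 0.5 or less, and all of these passed in limma. The limits on the ratios were set here. Those ratios come from the same log2 values, so their passing is no separate support for the calls. Of 24 gene lists, 14 were shifted with camera's preset correlation and 3 with an estimated correlation.

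The count of 1442 changed with every array left out. It was 925, 3727 and 851 without control replicates 1, 2 and 3 and 754, 679 and 654 without heat replicates 1, 2 and 3. Fewer arrays weaken a test at the same spread, so the drops do not by themselves mark an array as influential. Without control replicate 2 the count rose instead, and all 1442 calls were kept. The deviations of that array from its group mean had an SD of 0.27, against 0.16 to 0.21 on the other arrays. The count was 139 with the labelled age as a covariate, but the labelled ages rise by 1 day from each array to the next and differ from the design text, so whether they measure age is not given in the sources used here. Every heat label is also older than every control label, so age and group are hard to separate in that fit. This widens the error of the heat difference, and the drop does not show that age accounts for the calls. The share of lower calls was 63% as deposited, 56.3% after quantile normalization and 49.1% after cyclic loess, and 53.3%, 73% and 47.1% without control replicates 1, 2 and 3 and 48.5%, 45.4% and 42% without heat replicates 1, 2 and 3. Because the falls were smaller than the rises, a weaker test alone can lower this share.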

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

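The tests on plastid-encoded probe sets and those after cyclic loess, and the interval with age, were chosen after the results they bear on were seen. The 25S ribosomal RNA probe set, one of the array's control probe sets and so outside the limma test, stood out because every heat array lay above every control array. It read 9.23 ± 0.30 in controls and 10.02 ± 0.05 after heat (SD, n = 3), a log2 difference of 0.79. Mature ribosomal RNA has no poly(A) tail, while labelling reactions commonly start from poly(A). The 18 hybridization spike probe sets, added to each array from outside, read 7.61 ± 1.05 in controls and 8.20 ± 0.42 after heat, and the 24 Bacillus spike probe sets 4.07 ± 0.17 and 4.11 ± 0.08. The log2 gap between 3' and 5' probe sets, a sign of RNA integrity, also parted the groups for actin (1.84, 1.82 and 1.95 on control replicates 1 to 3, 1.62, 1.72 and 1.72 on heat replicates 1 to 3) and, in the other direction, for ubiquitin (0.07, 0.25 and 0.07, then 0.26, 0.32 and 0.28), but not for GAPDH (-0.199, -0.449 and -0.341, then -0.359, -0.408 and -0.217).

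Mitochondrial transcripts, which are also mostly without stable poly(A) tails, were higher on the heat arrays. Their median level was 1.80, 1.999 and 1.86 on control replicates 1 to 3 and 2.21, 2.29 and 2.34 on heat replicates 1 to 3. The lower quartiles of the arrays were 1.76 to 1.93, so many mitochondrial values lay near the bottom of the range. There a value cannot be told from background. Of 52 probe sets, 32 (61.5%) had all heat arrays above all controls, against 10.4% of all probe sets and 5% by chance. A level-dependent difference between the arrays is argued against as the whole of it, since cyclic loess left the mitochondrial median at 0.38 (95% bootstrap interval over probe sets 0.28 to 0.51, against 0.40 as deposited). A larger yield of tail-less RNA of every kind in the heat reactions would raise plastid transcripts alike and cannot be told apart. The 71 plastid-encoded probe sets had a median difference of -0.0028 as deposited (interval -0.04 to 0.07) but 0.14 after cyclic loess (interval 0.10 to 0.22). The latter interval reaches past 50% of the mitochondrial median there (0.19), and the 25S probe set was higher too. Plastid median levels were 7.69 to 7.96 on the arrays, far above the mitochondrial ones, so these lists are not matched in level. With the labelled age, which rises by 1 day from array to array, as a covariate the mitochondrial list passed at camera's preset correlation with a median of 0.31 (interval 0.17 to 0.58). That interval reaches below 0.20, 50% of the deposited median. Without the covariate, the list did not pass with an estimated correlation (camera adjusted p = 0.0514). Heat, age, RNA integrity, and array or labelling batches, which the labels do not give, stay open.

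For the counts themselves, the 6 arrays can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split called 1442 probe sets and was the 1 split of 10 with a count that large, the highest other split calling 0. Every other split mixes heat and control arrays within its groups, so the heat difference widens its spread and a count of 0 there is no fair comparison. The real split shifted 14 gene lists, again the 1 largest of 10, while the highest other split shifted 11. Every other split has more heat arrays in one group than in the other, so part of the heat difference remains in it. These list counts therefore do not measure false calls.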

How the results depend on the processing

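Cyclic loess, the organelle list rules and the run with the 3 omitted list members, which changed no list call, were chosen after the data were seen. Against 1442 changed probe sets (533 higher, 909 lower; 391 and 352 by at least 1), leaving out single arrays gave 654 to 3727 in all, 371 to 1008 higher, 275 to 2719 lower and 184 to 750 lower by at least 1. The highest of each came without control replicate 2. The labelled age as a covariate left 139 in all, 129 higher and 10 lower, the same counts holding at a size of at least 1. Without moderation the counts were 357 in all, 245 higher and 112 lower, and 216 higher and 46 lower by at least 1. A test against a log2 difference of 1 called 230, of which 212 were higher and 18 lower. At the same spread, leaving out an array or adding the labelled age weakens the test, yet the counts rose without control replicate 2. The causes of these moves were not tested. Apart from the replicate block below, each other setting kept these counts within a factor of 1.5, and the values of the authors' table are the same numbers and so test nothing. Over the settings run, 0 of the 1442 changed sign. Median centring raised the median difference of all probe sets by 0.11, which moves the balance of calls by construction, and called 49.7% higher, and cyclic loess 50.9%, against 37%.

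The replicate numbers did not pair the arrays. Deviations of same-numbered arrays from their group means correlated at -0.26, -0.24 and -0.24, no array correlating best with its own number. With the replicate block 806 probe sets were called, 410 of them lower.

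Of 24 lists 14 were shifted, and 3 with an estimated correlation. Of 68 named genes that changed, 64 passed after cyclic loess, 65 after median centring, 67 after quantile normalization, 52 with the block, 32 with age and 51 to 68 with an array left out, and 0 turned direction. Turns of a gene's sign or of a list test's direction occurred only in results that had not passed. HSFA1A was 0.0229 and LHY 0.0214 after median centring, BIP3 -0.0403 after quantile normalization and -0.0505 after cyclic loess, and HY5 -0.36 with age. With arrays left out, BIP3 ran from -0.0499 to 0.15, HY5 from -0.10 to 0.27, LHY from -0.25 to 0.19, SEN1 from -0.12 to 0.30 and PP2AA3 from -0.0763 to 0.18. List medians where the test's direction turned were, for auxin, 0.11 (median centring), 0.0009 (quantile), 0.0022 (trend and robust, and fry) and 0.0108 (cyclic loess), for light signalling -0.13 (quantile), -0.28 (without the lower-level probe sets) and -0.11 (cyclic loess), for jasmonate -0.45 (age) and 0.0702 (fry), for plastid-encoded genes -0.0775 (age) and -0.0028 (fry), and for reference genes 0.042 (age) and 0.0613 (cyclic loess). With arrays left out, medians ran from -0.0229 to 0.0681 for auxin, -0.30 to -0.12 for light signalling, -0.43 to 0.0094 for root markers -0.0589 to 0.13 for jasmonate, -0.28 to 0.0265 for galactinol and trehalose, -0.0486 to 0.0617 for plastid-encoded genes and -0.14 to -0.0635 for reference genes. The promoter motif test was not run because no genome was used here.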

Other observations

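The gene families in this paragraph were looked at after the list results were seen. Symbols sharing a stem formed 155 families of at least 10 probe sets, of which 8 were shifted (camera with preset correlation, adjusted over the families) and 0 with an estimated correlation. Besides the heat shock families, KCS genes, which encode 3-ketoacyl-CoA synthases that elongate very-long-chain fatty acids for waxes and membranes, were lower, with 6 of 19 falling and 0 rising (median -0.54, adjusted p = 0.0104, and adjusted p = 0.91 with an estimated correlation). KCS19 fell by 2.11 (SE 0.16, limma adjusted p = 0.000266), KCS20 by 1.19 (SE 0.14, adjusted p = 0.0025) and KCS1 by 1.85 (SE 0.33, adjusted p = 0.0169). The KCS1 call ended without control replicate 1 (-1.64) or 3 (-1.72) or heat replicate 2 (-1.597) or 3 (-1.95; adjusted p up to 0.0687). Among 20 probe sets with EXPA symbols, for expansins, 8 fell and 0 rose (median -0.49, adjusted p = 0.007, and 0.729 as adjusted p with an estimated correlation). Histone H2A genes of the HTA family had 3 of 10 falling, HTA13, HTA2 (-1.72, SE 0.15) and HTA10 (-1.29, SE 0.15), and 0 rising (median -0.37, adjusted p = 0.0227, and adjusted p = 0.91 with an estimated correlation). The 30 XTH genes, for xyloglucan endotransglucosylases, were not shifted (3 fell, median -0.13, adjusted p = 0.491). After cyclic loess the KCS and EXPA shifts passed (adjusted p = 0.00382 and 0.00497). Those of HTA (0.063), of the translation initiation factors EIF (0.145), of the galacturonosyltransferases GAUT (0.0911) and of the TCP stem (0.0911), which mixes transcription factors with a chaperonin subunit, did not.

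The tests with arrays left out and with only the called differences kept were chosen after the result was seen, and cyclic loess after the level-dependent difference was seen. With probe sets in 10 bins by mean level, the median difference was 0.07 in the dimmest bin and -0.19 in bin 7. After cyclic loess the count of lower over higher calls was 0.965, against 1.71 as deposited, as a level-dependent difference would give. That rescaling left a ratio of 1.66 in values that kept only the called differences, so the called differences alone do not lead it to even out the calls. The group difference of all other probe sets was removed there, so this test cannot show what the rescaling does to a broad shift. Control replicate 2 alone is argued against as the source, since without it the ratio was 2.7, but the ratio changed with each array left out (1.14 and 0.891 without control replicates 1 and 3, 0.943, 0.83 and 0.726 without heat replicates 1, 2 and 3). A broad shift of mid-level transcripts with heat would be removed by cyclic loess too, so heat stays open.

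Both tests of control replicate 2 were written before their values were seen. Control replicate 2 stood apart from the other controls, with correlations of 0.976 and 0.978 against 0.988 between the other controls, and with hybridization spikes at 8.81 against 7.08 and 6.93 (7.94 to 8.68 on the heat arrays) and an upper quartile of 4.57 against 4.78 and 4.89 (4.55 to 4.63 on the heat arrays), so its spread of intensities was nearer to that of the heat arrays. Heat-exposed tissue or RNA in that sample is argued against, since the 129 probe sets raised by at least 3 lay not above but below the other controls there, by a median of -3.9% of their heat difference (95% bootstrap interval -6.59 to -2.11). Another share of root tissue could not be settled, as the 8 root markers deviated by a median of -0.42 (interval -1.63 to 0.16) while the photosynthesis list deviated by 0.19. The root markers did not move together. CASP1 deviated by -1.89, IRT1 by -1.63, TIP2;3 by -1.56 and PYK10 by -0.69. EXPA18 (-0.16) and EXPA7 (-0.02) deviated little, and SHV2 (0.19) and NRT2:1 (0.16) were higher. The design gives this array no treatment of its own. Its labelled age of 17 days lies between the 16 and 18 days of the other controls, and an effect of age on it was not tested.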
